A study of Mus musculus with 4 samples.

How the data were processed

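MicroRNA (miRNA) levels were measured in epithelium peeled from the Peyer's patches of female BALB/cA mice, 10 weeks old and kept specific pathogen free. Per the labels, the tissue was soaked in 30 mM EDTA for 20 min, sheets of follicle-associated epithelium (FAE) and villous epithelium (VE) were lifted off with a 29G needle, and total RNA was extracted with the mirVana kit. The labels disagree on the temperature of the EDTA step, and no cell sorting is described in them. There were 2 groups, FAE and VE, with 2 arrays each, and each array's group and replicate number came from its title. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

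The arrays were Agilent mouse miRNA arrays, release 12.0, with 1 colour (Cy3). Per the file headers, the scans were read with Agilent Feature Extraction 10.1.1.1, and the deposited processed signal is a spot intensity after background subtraction, on a linear scale and with no normalization between arrays. Values below 0 occur for spots dimmer than the background. The series value table deposited by the authors held the same numbers, with a largest difference of 0 on every array and medians of 1.80 and 1.20 (FAE) and 1.38 and 0.77 (VE) in intensity units, so it was linear and not centred. The table had 0 columns of other samples. The design file behind the arrays names the build mm9. The gene table used for names is of the assembly GRCm38, so no coordinates are given and the table served only for names and for which miRNA genes are neighbours (start positions within 50 kb). Of the 611 mouse miRNAs on the array, 590 matched a gene in that table by name, as did 195 of the 200 tested.

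Control spots (715 per array) were left out, as were 301 to 331 of the 13000 other spots per array that the scanner software had marked as outliers. The remaining spots of a probe, of which the array prints 5 to 20, were averaged. A probe counted as detected on an array where over 50% of its used spots were marked well above background. Each array was divided by its 75th percentile over the 327 mouse probes detected on all 4 arrays, values under a floor of 0.0400 of that percentile were set to the floor, and log2 was taken, so that a level of 0 is the percentile and -4.65 the floor. Levels at the floor have no order. The 607 miRNAs with several probes were represented by the probe with the highest mean over the 4 arrays. Among tested miRNAs, 164 had several measured probes, and in 4 of them the probes disagreed on the direction of the difference. Levels of different probes are not compared as amounts, because probes differ in how well they bind.

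The 200 miRNAs detected on both arrays of at least 1 group were compared between FAE and VE with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. No p-value below 0.333 can come from an exact permutation of 2 against 2 arrays, so every call rests on limma's pooling of the spread over miRNAs. A miRNA not well above background on any array of a group has only a bound there. Its difference is given as "at least N-fold", the brighter group's mean against the mean, per array, of the lowest signal of a detected probe or the dim probe's own signal where that was higher. That limit is each array's own and on VE array 1 lies below the common floor, so a bound can slightly exceed the fold between means set at the floor, which is itself a bound. Before the data were examined, 22 lists of miRNAs were fixed: families, genomic clusters and markers of epithelial and other cell types. The 14 lists with 3 or more tested members were tested with camera (preset correlation 0.01, adjusted over the lists, and again with an estimated correlation). The preset value is an assumption. The estimated correlation is poorly determined, because the fit leaves 2 residual degrees of freedom. The miRNAs named in the text follow a rule fixed at the same time: among those past the threshold whose FAE and VE arrays do not overlap, the 10 with the largest difference in each direction. If fewer than 10 passed in a direction, those were filled up to 5 with the next by unadjusted p. The 5 highest signals in each group and the 3 tested members with the highest mean in each list were also named.

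On simulated arrays made from the spread of the FAE and VE comparison (50 simulations of 200 miRNAs, 10 changed at each size), the same fit recovered 39.6% of miRNAs changed by 1 log2 unit, 76.4% of those changed by 2 and 84.8% of those changed by 3. It called 0.658% of the unchanged ones. A list shifted by 1 log2 unit was called in 100% of simulations and the other lists in 0.462%, but the simulated members varied independently, which favours the preset correlation.

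All 4 arrays lay on 1 slide and in 1 scan, so no fit with either as a block was possible. The alternatives, whose effects are given in the closing section, changed the scaling, the background correction, the filter on dim miRNAs, the floor, the summary over probes, the variance model, the replicate block and the set test, and left out each array in turn. The files used here hold no mean spot signal, so the planned normexp background correction was replaced by one on the median spot signal (offset 50). That alternative, and one that left out miRNAs at the floor on both arrays of a group, were chosen after seeing the data. Probes for 39 viral miRNAs were kept out of the comparison.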

Results

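The data were miRNA profiles of the 2 kinds of epithelium of the mouse Peyer's patch, the lymphoid tissue of the small intestine. Follicle-associated epithelium (FAE) covers the lymphoid follicles and holds the antigen-sampling M cells, and villous epithelium (VE) covers the villi around them. Each group had 2 arrays, all on 1 slide. On the FAE arrays 212 and 201 of the 611 mouse miRNAs were detected (replicates 1 and 2), and on the VE arrays 189 and 179. On all 4 arrays 165 were detected, and on none 379. The 75th percentile of the commonly detected probes was 197 and 196 intensity units in FAE and 227 and 202 in VE, no spot was saturated, and the lowest signal of a detected probe was 7.54 to 8.41 units. Across the 200 tested miRNAs, which are not independent replicates, Pearson's r was 0.985 between the FAE arrays, 0.977 between the VE arrays and 0.917 to 0.961 between arrays of different groups. Having 2 arrays per group limits the precision of every value below. Levels are log2 scaled signals (0 is the array's 75th percentile, -4.65 the floor), given as mean ± SD with n = 2 per group, and names omit the prefix mmu.

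The comparison of FAE with VE asks which miRNAs set the epithelium over the follicles apart from that of the villi. The clearest difference was in miR-155, a miRNA made from the Bic transcript and induced in activated lymphocytes and myeloid cells. It stood at -1.57 ± 0.10 in FAE and was not well above background on either VE array, a difference of at least 8.60-fold (limma adjusted p = 0.000581). miR-34a, a transcriptional target of p53, was at -1.99 ± 0.30 in FAE and likewise not well above background in VE, at least 6.43-fold higher in FAE (limma adjusted p = 0.00162). For miR-155 and miR-34a both VE values were set to the floor, so the VE spread behind these p-values is 0 by construction. miR-193 and miR-365, whose genes Mir193a and Mir365-2 are neighbours on GRCm38, rose in FAE by 1.91 (SE 0.21) and 1.85 (SE 0.25) log2 units, 3.77-fold and 3.61-fold, with adjusted p of 0.00471 and 0.00923. miR-1224, which is spliced from an intron without Drosha, rose 3.65-fold, from 0.41 ± 0.17 in VE to 2.28 ± 0.24 in FAE (log2 1.87, SE 0.23, adjusted p = 0.00650).

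Dimmer miRNAs completed the 10 largest increases among those that passed. miR-207, miR-764-5p, miR-1196 and miR-346 were 2.86-fold, 2.78-fold, 2.45-fold and 2.40-fold higher in FAE, with adjusted p between 0.0363 and 0.0423. Each of these miRNAs was higher on FAE array 1 than on FAE array 2 (miR-207 at -1.96 and -2.62). Among the 50 dimmest tested miRNAs, FAE array 1 exceeded FAE array 2 by a median of 0.32. Across the alternatives the log2 changes of miR-207, miR-764-5p, miR-1196 and miR-346 fell as low as 0.31, 0.16, 0.30 and 0.03. miR-149 was at least 2.38-fold higher, with no VE array well above background (adjusted p = 0.0284, with a VE spread of 0 by construction). All of these had VE levels below -3, close to the floor, and miR-346 was well above background on 1 of the VE arrays. Outside the 10, miR-139-5p, miR-689 and miR-181d also passed in this direction, 2.14-fold, 2.11-fold and 2.09-fold higher with adjusted p = 0.0363 each.

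In the other direction only miR-101a, known to repress the histone methyltransferase Ezh2, passed in limma's test. It fell from -1.90 ± 0.03 in VE to -2.79 ± 0.00181 in FAE, a log2 change of -0.89 (SE 0.20, adjusted p = 0.0480). The next 4 by unadjusted p did not pass, each with a limma adjusted p of 0.0507. miR-143, abundant in smooth muscle and fibroblasts, was at -4.32 ± 0.11 in FAE and at 1.14 and -2.10 on VE arrays 1 and 2, which differ from each other by 3.24. miR-199a-3p, also of mesenchymal cells, and miR-224 were not well above background in FAE and were at least 2.51-fold and 1.66-fold higher in VE. miR-30e* differed by -0.89 (SE 0.22).

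In all, limma called 13 miRNAs higher and 1 lower in FAE among the 200, and 63 higher and 19 lower at an unadjusted p under 0.05. A further 38 (30 higher, 8 lower) had adjusted p between 0.05 and 0.06. The FAE arrays lay above both VE arrays for 99 miRNAs and below both for 58, together 78.5%. For a single miRNA without filter or ties, chance would give 33.3%. The tested miRNAs are not independent, and some lie at the floor on both arrays of a group through the filter. The 33.3% is therefore no test of the observed share. The median change was 0.21 and followed signal: it was 0.49 in the 50 dimmest of the tested miRNAs and -0.20 in the 50 brightest. Without FAE replicate 1, FAE replicate 2, VE replicate 1 or VE replicate 2 the counts were 0 and 0 each time (limma), with 43 and 2, 59 and 3, 22 and 45, and 31 and 24 miRNAs higher and lower at an unadjusted p under 0.05. Scaling to all mouse probes left 1 and 0 calls and turned the unadjusted split to 18 higher and 56 lower. Of the mouse probes 25.5% and 23.7% were detected in FAE and 21.7% and 20.7% in VE, so the 75th percentile over all of them lies near the detection limit. Normexp background correction left miR-1224 alone, with miR-155 at log2 0.69, miR-34a at 0.49 and miR-149 at -0.02. Its offset of 50 intensity units is above the median signal of the detected probes on every array, 33.4 to 38.5 units. The correction therefore shrinks the differences of dim miRNAs by construction.

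**Figure D1:**
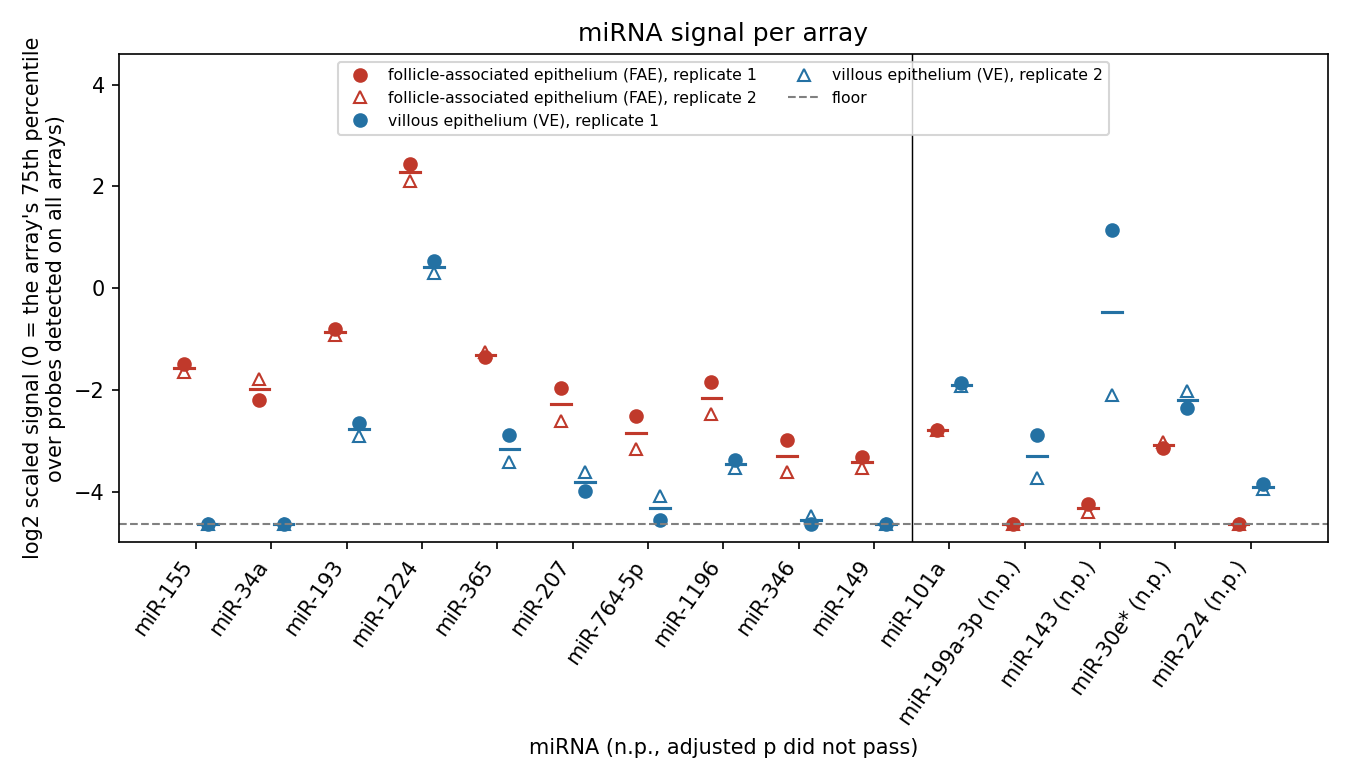
Log2 scaled signal (vertical axis, 0 is the array's 75th percentile over probes detected on all arrays) of the miRNAs named for their difference between FAE and VE (horizontal axis), with 1 point per array, short bars at the group means and a dashed line at the floor of -4.65. miR-155 and miR-34a lie at the floor on both VE arrays, and the VE arrays of miR-143 are spread over 3.24 log2 units, at 1.14 and -2.10.

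The strongest probes were much the same in both tissues. The 5 miRNAs with the highest signal were miR-21, miR-215, miR-194, miR-192 and miR-200b in both groups. miR-21, a miRNA induced by inflammation and in many tumours, was at 5.85 ± 0.21 in FAE and 5.39 ± 0.40 in VE, and limma's test did not separate them (log2 0.46, SE 0.27, adjusted p = 0.239). The log2 difference was -0.08 when scaled to all mouse probes and 0.17 to 0.74 without each replicate in turn. The probe signals of the 3 brightest miRNAs made up 40.9% and 43.3% of the summed signal in FAE and 46.0% and 49.0% in VE.

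Among the lists fixed beforehand, the enterocyte miRNAs fell together in FAE (camera adjusted p = 0.0342; adjusted p = 0.756 with an estimated correlation). miR-192, miR-194 and miR-215, abundant in intestinal epithelium and dependent on HNF factors, were lower in FAE on every array, with a median of -0.69. miR-215 was at 5.81 ± 0.08 in FAE against 6.57 ± 0.30 in VE (log2 -0.77, SE 0.23, adjusted p = 0.0581), miR-194 differed by -0.69 (adjusted p = 0.0627) and miR-192 by -0.49 (adjusted p = 0.149). None of the 3 passed over all miRNAs and 2 passed when adjusted over the list alone. The list's call ended with scaling to all mouse probes (median -1.23, adjusted p = 0.115), quantile normalization (median -0.13, adjusted p = 0.283), a trend in the variance (median -0.69, adjusted p = 0.0993) and without FAE replicate 1 (median -0.70, adjusted p = 0.0960) or FAE replicate 2 (median -0.68, adjusted p = 0.0909), over a range of 0.00247 to 0.756 in all alternatives.

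The let-7 family, high in differentiated cells, and the miR-30 family also fell together in FAE. All 9 let-7 members were lower, with a median of -0.37 (camera adjusted p = 0.0131; adjusted p = 0.756 with an estimated correlation), and let-7f, let-7a and let-7c differed by -0.37, -0.41 and -0.34. All 5 miR-30 members were lower, with a median of -0.49 (camera adjusted p = 0.0201; adjusted p = 0.756 with an estimated correlation), and miR-30c, miR-30b and miR-30e differed by -0.49, -0.42 and -0.49. No member of either family passed, over all miRNAs or adjusted over the list alone. Members of a family resemble each other in sequence and their probes can share signal, so a shared direction is not a set of independent observations. Scaling to all mouse probes gave let-7 a median of -0.91 and ended the miR-30 call (median -1.02, adjusted p = 0.0652, range over alternatives 5.77e-06 to 0.756). Since the change followed signal, members were also set against the 20 other miRNAs closest in signal, which left a median difference of -0.51 for the enterocyte list, -0.36 for let-7 and -0.41 for miR-30. For the enterocyte list, every comparator except miR-21 was dimmer than all of its members. The match therefore cannot remove a trend with signal from that list.

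The Sfmbt2 list is named for a rodent-specific run of repeated miRNA genes within an intron of the Polycomb gene Sfmbt2. Its members were taken by name (miR-297, miR-466, miR-467 and miR-669), and whether each lies in that intron was not checked. The list rose together in FAE. Of 35 members on the array 11 were tested and all 11 were higher, with a median of 1.08 (also 1.08 with the 2 members not well above background in VE at their bound) and a camera adjusted p of 0.00843, against 0.756 with an estimated correlation. No member passed over all miRNAs and 10 passed when adjusted over the list alone. miR-466f-3p, miR-466g and miR-467f differed by 0.91, 1.05 and 0.88 log2 units with adjusted p of 0.0566, 0.0507 and 0.0729. Members resemble each other in sequence and their probes can share signal, so they are not independent. All 11 were also higher on FAE array 1 than on FAE array 2, by a median of 0.76. The list's median was 0.55 when scaled to all mouse probes and 0.41 under normexp. With no filter it was 0.35, taken over all 35 members, with those at the floor on every array included. It was 0.69 without FAE replicate 1 and 1.44 without FAE replicate 2. The call ended without VE replicate 1 (median 1.04) or VE replicate 2 (median 1.08). The list's camera adjusted p ranged from 0.000168 to 0.756 in all alternatives.

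On the lists of markers of other cell types, only miR-155 passed over all miRNAs. Of the 6 tested leukocyte miRNAs miR-155 passed, 5 were higher in FAE, and the list did not pass (median 0.69, camera adjusted p = 0.112, 0.756 with an estimated correlation). With adjustment over the list alone 2 passed. miR-142-3p, made in all blood cell lineages, was at 3.04 ± 0.24 in FAE and 2.35 ± 0.54 in VE (log2 0.68, SE 0.31, adjusted p = 0.140), miR-142-5p differed by 0.63 and miR-342-3p by 0.70. Without each replicate in turn the list's median was 0.42 to 1.02 and miR-142-3p 0.30 to 1.07. The list passed under normexp correction (camera adjusted p = 0.0491) and with no filter on dim miRNAs (0.00996). Without the filter, 379 of the 611 miRNAs tested were detected on no array and 5 lists passed in each direction, so that pass says little about this list. Its adjusted p ranged from 0.00996 to 0.756 in all alternatives. The stromal list had 2 tested members, miR-143 and miR-199a-3p, given above. The endothelial miR-126-3p was not well above background in FAE and at -2.21 and -4.17 on VE arrays 1 and 2 (at least 2.74-fold higher in VE, adjusted p = 0.117). The erythroid miR-451 was at -3.84 ± 0.76 in FAE and -1.83 ± 1.05 in VE (log2 -2.01, SE 0.55, adjusted p = 0.0515). Its change was -2.76 to -1.27 without each replicate in turn. The 2 stromal members, miR-126-3p and miR-451 passed when adjusted over their lists alone, which for the endothelial and erythroid lists is a single test. Of the 4 muscle miRNAs on the array none was tested and 3 were detected, all on VE array 1 alone, and none of the 4 neural miRNAs was detected.

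Other epithelial lists with a set test did not pass. The miR-200 family, which maintains epithelial identity, had a median of -0.05 over 5 members (camera adjusted p = 0.307), with miR-200b at 3.80 ± 0.19 in FAE and 3.81 ± 0.25 in VE, a difference (-0.01) whose sign changed under background and probe alternatives, without FAE replicate 1 (0.12) and without VE replicate 2 (0.17). miR-200a and miR-200c differed by -0.05 (0.0716 without VE replicate 2) and -0.27. The endocrine list had a median of -0.22 (adjusted p = 0.225), with miR-375, of enteroendocrine cells, at -0.32, miR-7a at -0.22 and miR-7b at -0.19. The miR-183 cluster had a median of 0.54 (adjusted p = 0.246), with miR-96 at 0.54, miR-183 at 0.54 and miR-182 at 0.78, and 1 of the 3 passed when adjusted over the list alone. The NF-kB-responsive list and the family of miR-34 and miR-449 had 2 tested members each and no set test. In the first, miR-21 is given above and miR-146a differed by -0.21 (adjusted p = 0.520). In the second, miR-34b-3p was at least 1.75-fold higher in FAE (adjusted p = 0.0640, reversed to log2 -0.10 under normexp), and both tested members passed when adjusted over the list alone.

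The remaining families and clusters with a set test did not pass either. All 10 tested members of the miR-17 to miR-92a cluster and its paralogs, driven by Myc, were higher in FAE with a median of 0.23 (camera adjusted p = 0.437), but scaling to all mouse probes turned the median to -0.31, and the list passed without VE replicate 2 (adjusted p = 0.0184), under normexp (0.0491) and with no filter (0.000377), over a range of 0.000377 to 0.918 in all alternatives. miR-19b, miR-92a and miR-20a differed by 0.23, 0.13 and 0.23. The clusters of miR-23, miR-27 and miR-24 had a median of 0.29 (adjusted p = 0.609, -0.25 when scaled to all mouse probes), with miR-23a at 0.74 and miR-27a at 0.88 (adjusted p = 0.0518 and 0.0507) against -0.19 for miR-23b, and 2 of 5 passed when adjusted over the list alone. In the miR-181 family (median 0.43, adjusted p = 0.445, -0.09 under quantile normalization, -0.08 under normexp and -0.11 when scaled to all mouse probes) miR-181d rose 2.09-fold, miR-181c differed by 0.64 and miR-181a by -0.19, and 2 of 4 passed when adjusted over the list alone. The miR-29 family had a median of 0.08 but a mean of -0.05 and a downward test (adjusted p = 0.517), its median being -0.46 when scaled to all mouse probes, with miR-29b, miR-29a and miR-29c at 0.08, 0.14 and -0.38. miR-16, miR-15b and miR-15a differed by -0.15, -0.16 and -0.25 (list median -0.20, adjusted p = 0.145). In the group of miR-10, miR-99, miR-100 and miR-125 (median -1.01, adjusted p = 0.168), miR-10a, miR-10b and miR-125b-5p differed by -1.01, -0.14 and -1.03, the last reversing to 0.05 without VE replicate 1. That list passed without VE replicate 2 (median -1.40, adjusted p = 0.0392), while without VE replicate 1 its median was -0.0122 (adjusted p = 0.889), and miR-10a was -1.62 to -0.41 without each replicate in turn. Of 53 members of the imprinted Dlk1-Dio3 cluster 2 were tested, too few for a set test, miR-494 at -0.14 and miR-376b at 1.43 (adjusted p = 0.844 and 0.0830), and without each replicate in turn miR-494 was -1.02 to 0.74 and miR-376b 0.71 to 2.16, the latter 0.20 under normexp. With an estimated correlation no list passed (camera adjusted p 0.756 to 0.819). That correlation was 0.978 for the Sfmbt2 list, 0.976 for the enterocyte list, 0.892 for miR-30 and 0.543 for let-7. It rests on 2 residual degrees of freedom, so failing with it does not decide whether a list changed.

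**Figure D2:**
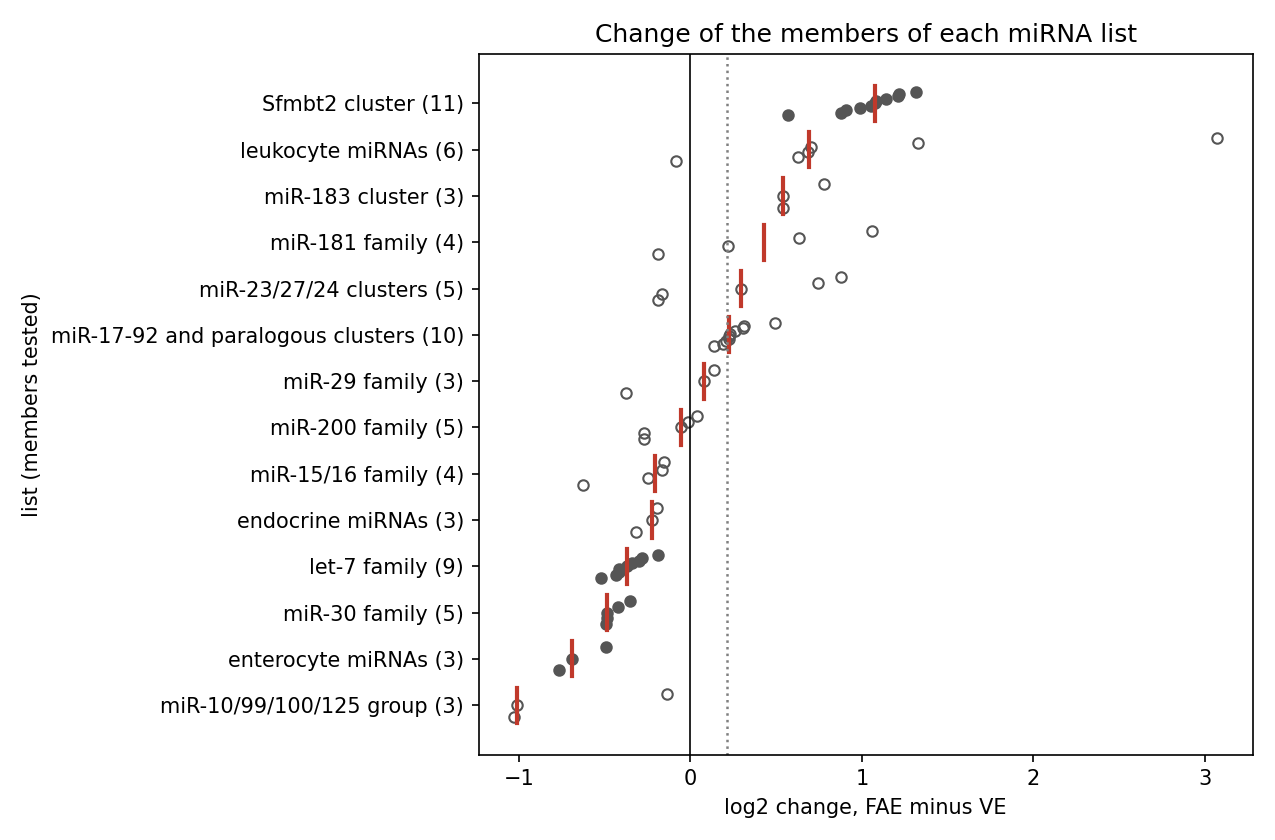
Log2 change from VE to FAE (horizontal axis) of each tested member of the 14 lists with a set test (vertical axis, number of members in brackets), with red bars at the list medians, filled points for lists past camera's threshold, a solid line at 0 and a dotted line at the median of all tested miRNAs, 0.21. The Sfmbt2 list has the highest median, 1.08, and of the 4 lists past the threshold the other 3, with medians of -0.37, -0.49 and -0.69, lie below 0. None of the 4 passed with an estimated correlation (camera adjusted p = 0.756 each).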

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

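All tests of explanations in this part were chosen after the results they bear on had been seen. The array carries probes for 39 viral miRNAs, which the comparison did not use, and 3 of them were detected. The signal for mghv-miR-M1-2, of murine gammaherpesvirus, was well above background on all 4 arrays with a mean intensity of 13.8 (17.4 and 13.9 in FAE, 12.5 and 11.2 in VE). The signal for mcmv-miR-m88-1, of murine cytomegalovirus, had a mean of 8.75 and was well above background on 2 arrays. The signal for mcmv-miR-M23-1-5p had a mean of 7.15, at 22.7 on VE array 2 and 1.55 to 2.55 on the others. The labels name no infection and no control for these probes, and cross-hybridisation of mouse RNA was not tested.

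miR-155 and miR-150 (named after its values were seen, and not passing at a limma adjusted p of 0.0507) were higher in FAE on every array, and neither was well above background in VE. Both are on the leukocyte list, of which miR-142-3p, miR-142-5p, miR-342-3p and miR-223 were well above background on both VE arrays too, and the labels describe no sort that would remove leukocytes. More leukocytes of an unchanged kind would raise all of their miRNAs alike, but the difference between miR-155 and miR-142-3p within an array changed by at least 2.39 log2 units (a lower bound, with miR-155 at the floor in VE), against 0.77 between the VE arrays, which is the spread of miR-142-3p alone. Under normexp correction the changes of miR-155 and miR-142-3p were alike, 0.69 and 0.70. Its offset of 50 compresses dim signals such as miR-155 (-1.57 in FAE) more than bright ones such as miR-142-3p (3.04 in FAE). That likeness therefore decides nothing. The values thus argue against more leukocytes of one kind only without that offset. They do not exclude it, since the contrast was chosen after the result and rests on 2 arrays per group and a single reference miRNA. A shift in the kinds of leukocytes may contribute: for miR-150 the corresponding change is also only a bound, at least 0.64, which decides nothing, and expression of miR-155 in epithelial cells was not tested.

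The Sfmbt2 list, whose members were taken by name, rose by a median of 1.08, or 0.87 above the median of all tested miRNAs. A background added alike to all probes on the FAE arrays would account for little of it. Viral probes below detection rose by a median of 0.384 intensity units, 1.06% of the 36.0 units of the list. Those viral probes were chosen for being below detection, so background that depends on a probe's sequence was not tested. The viral mghv-miR-M1-2, detected on all arrays, was at 17.4 and 13.9 in FAE and 12.5 and 11.2 in VE. The list's median change was 0.41 under normexp correction and 0.55 when scaled to all mouse probes. A trend with brightness leaves most of it, since the members exceeded the miRNAs closest in signal by a median of 0.79, 11 of 11 being above. A property of single RNA samples, such as RNA quality, may account for part or all of it, because FAE array 1 exceeded FAE array 2 by a median of 0.76 while FAE array 2 exceeded the VE mean by 0.69. A difference between the tissues stays open and was not tested apart from this.

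The detected stromal, endothelial and muscle miRNAs had their highest values on VE array 1, and none passed over all miRNAs. All 7 members of the 3 lists detected on any array were higher on VE array 1 than on VE array 2, by a median of 1.39, a bound set by miR-145. The rule of detection on any array favours no array. miR-1, miR-133a, miR-133b and miR-145 were detected on VE array 1 alone, so for them being higher there and being detected there are the same observation. miR-143, miR-199a-3p and miR-126-3p were detected on both VE arrays and were also higher on VE array 1. All 7 rest on the same arrays and are not independent. More underlying stroma or muscle in that sample would give this, but was not tested apart. The brightest were miR-143 (1.14 against -2.10) and miR-1 (-1.43), and miR-1, miR-133a, miR-133b and miR-145 were at the floor on VE array 2 and in FAE alike. VE array 2 still exceeded the FAE mean by 2.21 for miR-143, so a tissue difference, or a smaller amount of such cells in both VE samples, remains open. The erythroid miR-451 went the other way, lower on VE array 1 by 1.49.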

How the results depend on the processing

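Each result was recomputed under the alternatives, of which normexp correction and leaving out miRNAs at the floor were chosen after seeing the data. Named miRNAs kept direction and side of the threshold in 881 of their recomputations, were weaker in 107, stronger in 61 and reversed in 22. Lists did so in 221, 15, 10 and 6. Most named miRNAs and lists did not pass in the main setting, so most kept results are ones that stayed not passing. Every weaker result is a main call that no longer passed. Among the main calls in this count, miR-155 passed most often, in 10 of 15 alternatives, and miR-149 least often, in 5 of 15. For the counts, the cause was not tested unless stated. The median change over tested miRNAs, 0.21, became -0.32 with scaling to all mouse probes, 0.0884 without scaling, -0.0785 with quantile normalization and -0.0953 with normexp. The median of the shifts of single miRNAs was -0.54, -0.13, -0.33 and -0.0843, and quantile normalization moved miRNAs by different amounts (enterocyte list from -0.69 to -0.13). Calls higher and lower in FAE were 1 and 0 with all mouse probes, 2 and 0 without scaling, 1 and 0 with quantile normalization, 1 and 0 with normexp, 1 and 1 without a filter (611 tested, 379 of them detected on no array, so that many have no spread and the fit is unreliable), 35 and 8 over miRNAs detected on all 4 arrays, 26 and 4 without miRNAs at the floor (both fewer tested), 38 and 7 with the floor lowered 4-fold, 6 and 0 with the mean of probes, 48 and 6 with the total gene signal, 55 and 15 with a trend in the variance, and 13 and 1 with the series table. Of the 14 calls 10 were tested over miRNAs detected on all 4 arrays and 11 without those at the floor. Wherever they were tested they kept their sign, except miR-149 under normexp, and 14 of 14 were kept with the lower floor, the total gene signal and the trend. Without FAE replicate 1, FAE replicate 2, VE replicate 1 or VE replicate 2 the counts were 0 to 0 in both directions (limma; fewer samples, with the lone sample assumed to vary like the other group), with a smallest adjusted p of 0.0715 to 0.131. Lists higher in FAE were 3 with normexp, 5 without a filter, 0 with camera's estimated correlation and 0 to 1 without each replicate. Without a filter the endocrine, miR-183, leukocyte, miR-17, miR-15 and miR-181 lists passed as well. Lists lower were 1 with all mouse probes, 2 with quantile normalization, 2 with a trend in the variance, 5 without a filter and 0 with the estimated correlation.

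With the replicate number as a block, 48 miRNAs were higher and 9 lower, and 0 lists lower (adjusted p = 0.0937 for let-7 and 0.109 each for the miR-30 and enterocyte lists). Deviations of same-numbered arrays correlated at 0.175 over 2 pairs, and the labels name no shared animal or day, so the numbers were not taken as pairs. A block on slide or scan and normexp on the mean spot signal were not run (1 slide, and no such column in the files used here).

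Reversals (for a list, of the direction of its test): with all mouse probes miR-21 (-0.0793), miR-19b (-0.31), miR-92a (-0.40), miR-20a (-0.31), miR-29b (-0.46), miR-29a (-0.40) and the lists of miR-17 to miR-92a (-0.31) and of miR-23, miR-27 and miR-24 (-0.25), all moving by about the median shift of single miRNAs. List medians that changed sign while the test kept its direction were, with all mouse probes, those of the miR-29 (-0.46) and miR-181 (-0.11) lists, without scaling the miR-29 list (-0.0494), without VE replicate 1 the miR-29 list (-0.00656) and without VE replicate 2 the miR-200 list (0.0716). Without scaling miR-29b (-0.0494). With quantile normalization miR-200a (1.33e-16, which is 0 but for rounding) and the miR-181 list (-0.0918). With normexp miR-149 (-0.0237), miR-200b (0.0339), miR-181c (-0.0342), miR-34b-3p (-0.10) and the lists miR-29 (0.11, a median of unchanged sign) and miR-181 (-0.0765). With the mean of probes and the total gene signal miR-200b (0.0119 and 0.0677). Without each replicate in turn the ranges were -0.19 to 0.17 for miR-200b, -0.18 to 0.0716 for miR-200a, -0.49 to 0.0642 for miR-146a, -0.00746 to 0.28 for miR-92a, -0.00656 to 0.16 for miR-29b, -2.11 to 0.0521 for miR-125b-5p, -1.02 to 0.74 for miR-494, and medians of 0.20 to 0.38 for the list of miR-23, miR-27 and miR-24, whose test alone changed sign. Apart from the block, let-7 lost its call only with the estimated correlation. The enterocyte call was also lost with a trend in the variance (0.0993).

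Detection counts for FAE arrays 1 and 2 and VE arrays 1 and 2 were 238, 229, 218 and 209 with at least 1 spot well above background, and 252, 236, 226 and 214 with the scanner software's gene flag. Signal over background limits the dimmest miRNAs most: both VE values of miR-155, miR-34a and miR-149 are at the floor, so their spread there is 0 by construction.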

Other observations

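The genes of miR-181c, miR-181d, miR-23a and miR-27a are neighbours on GRCm38 (adjacent pairs within 50 kb), and these miRNAs were picked out after their values were seen, so the contrast with their paralogs restates that choice and tests nothing. miR-181d rose, while miR-23a, miR-27a and miR-181c had adjusted p of 0.0518, 0.0507 and 0.0633. The paralogs at other loci, miR-181a, miR-181b, miR-23b and miR-27b, differed by -0.19, 0.22, -0.19 and -0.17, none passing. Mir24-2 lies within 50 kb of Mir27a, and miR-24, which a gene of the other cluster also makes, differed by 0.29 (adjusted p = 0.299). Under normexp correction miR-23a and miR-27a differed by 0.67 and 0.77, miR-181d by 0.11 and miR-181c by -0.0342.

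miR-193 and miR-365 rose by similar amounts, and their genes Mir193a and Mir365-2 lie within 50 kb of each other on GRCm38. The related Mir193b lies beside Mir365-1, and miR-193b was not well above background on any array.

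miR-494 stood at 0.93 and -0.83 on VE arrays 1 and 2 against -0.14 and -0.04 in FAE, and miR-125b-5p at -1.73 and -3.89 against -3.80 and -3.88. miR-10a was at -2.64 and -1.43 on the FAE arrays and -0.64 and -1.41 on the VE arrays.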
